A study of Mus musculus with 8 samples.

How the data were processed

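The series holds 8 samples of female C57BL/6 mouse bone marrow-derived dendritic cells, 4 in medium and 4 with SCF, from experiments BC, D2, E and I. Groups and experiments were taken from the sample titles. Per the labels' protocols, bone marrow cells were cultured for 7 days at 21% oxygen with GM-CSF at 20 ng/ml and purified on CD11c magnetic beads to at least 98%. They then spent 2 days at 2% oxygen (about 14 mmHg) with GM-CSF before SCF (100 ng/ml) was added or left out for a final 6 hours. Total RNA was labelled with biotin and hybridised to Affymetrix whole-transcript arrays, 1 array per culture and 1 colour.

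The deposited table holds 1 intensity per probe set and array, made with RMA per the submitters' processing notes. The version of RMA, its software and any filter are not given in the sources used here. The deposited intensities were on a linear scale, as their values showed, with a maximum between 3588 and 4252 per array, so log2 was taken before any test, with no pseudocount and no further normalization. Of 41345 probe sets, 23521 had exactly 1 gene symbol in the platform annotation given, 1814 had several and 16010 were unnamed here. Entrez numbers of 23328 single-symbol probe sets were found in a RefSeq gene table (assembly GRCm38.p6, used for names only), and 0 symbols differed from it. Probe sets with several symbols were tested but not named. The table gives no detection call or background level, so signal over background is unknown. In place of such a call, probe sets with a symbol were tested only where their mean log2 intensity over all 8 arrays reached the median of those means, 4.05 (16.6 on the linear scale), which left 12668 probe sets. A gene with several probe sets was represented by the one with the highest mean, which gave 11351 genes. No 2 arrays held the same values. The number of arrays, 4 per group, limits the precision, and the median SE of a log2 fold change was 0.06.

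The design text of the series states that the cells of each experiment were generated and purified together and then cultured with or without SCF, so the arrays are paired by experiment. After removal of the group means, arrays of the same experiment correlated at 0.46 in BC, 0.41 in D2, 0.42 in E and 0.36 in I across the tested probe sets. Among the arrays of the other group, each array correlated best with that of its own experiment. Arrays of the same group were not compared in this way. Without removal of the group means, 7 of 8 arrays were closest to the other array of their experiment over the tested probe sets, but 1 of 8 over all 41345. SCF was compared with medium by lmFit and eBayes of limma 3.58.1 in R 4.3.3, with experiment as a fixed block, two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. The fit leaves 3 residual degrees of freedom, or 7.39 with the prior. Confidence intervals are at 95% and are not adjusted for the number of probe sets.

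Before the data were examined, 44 gene lists with 849 symbols were fixed, covering signalling downstream of the SCF receptor, hypoxia and metabolism, immune functions, growth, RNA quality and markers of 13 cell types. On the arrays 747 of the symbols were named and 590 were tested. The 39 lists with at least 5 tested members were compared by camera with its preset correlation of 0.01, beside camera with an estimated correlation and fry, each adjusted over the lists. Camera asks whether a list's genes shift relative to all other genes, while fry asks whether they move on balance in 1 direction and does not compare them with other genes. With an estimated correlation, camera takes its p from the residual degrees of freedom of the fit instead of the number of genes. The mean of a list was also taken per experiment and tested by an exact sign-flip permutation over the 4 pairs. List symbols that match an unrelated gene only through a synonym were left unmatched.

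The genes to be named were also fixed beforehand. Kit, Kitl, Il6, Jag2, Vegfa and Itgax were named whatever their values. The 12 largest increases and decreases past the threshold with the same sign in all 4 experiments would have been named, but 0 genes qualified. The fallback of the 8 smallest p-values in each direction among genes changed at least 1.5-fold with the same sign in all 4 experiments also gave 0 genes. From each list described, up to 4 members with the smallest unadjusted p were named, and every passing member where 5 or fewer passed. Other genes are said to have been chosen after their values were seen.

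The fit was tested on simulated data with the real means and experiment effects, residual variances drawn from the prior fitted to the real arrays, and 200 changed probe sets in each of 20 simulations. Called probe sets that had not been changed made up 5.01% of all calls. These variances need the fit to the real arrays. Taking each probe set's shrunken variance instead, as was done at first, gave 7.11% false calls among all calls and recovered 97.8% of changes of 1.41-fold and 31.7% of those of 1.19-fold, among 12668 probe sets. The draw from the prior replaced it after that result was seen. Both draws treated probe sets as independent of each other. In simulated lists of 20 independent genes shifted by a log2 difference of 0.1, camera with its preset correlation called 20 of 20, and 1 of 780 unchanged lists. These counts do not cover lists whose genes move together. In the real data the estimated correlation was 0.27 for pattern recognition receptors and 0.24 for dendritic cell maturation genes.

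Alternatives fixed before the data were examined were the fit without the block, experiment as a random block, equalized array medians, a repeated quantile normalization, array weights, a variance trend, no filter, a filter at the 75th percentile and leaving out each experiment. For gene calls, an adjusted p of 0.10, unnamed probe sets and a plain paired statistic were added, and for lists, an estimated correlation, fry, ranks and the mean of a gene's probe sets. Differences between experiments were tested with limma's F test over the 4 experiments in the same fit. Figures were drawn with matplotlib.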

Results

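RNA was measured in mouse dendritic cells grown from bone marrow with GM-CSF, the growth factor that drives this culture, and held under low oxygen with or without stem cell factor (SCF), the ligand of the receptor tyrosine kinase Kit. The cells came from 4 separately run experiments named BC, D2, E and I. In each experiment the purified CD11c-positive cells were kept at 2% oxygen with GM-CSF for 2 days, and then either received SCF at 100 ng/ml or were left in medium for 6 hours. Each of the 8 cultures was read on 1 Affymetrix array, which gave 4 medium and 4 SCF arrays in 4 pairs. The arrays held 41345 probe sets, and their median intensity lay between 13.3 and 13.9 on the linear scale. Pearson's r between the log2 values of any 2 arrays lay between 0.9902 and 0.9949, across probe sets that are not independent of each other. The number of arrays, 4 per group, limits the precision.

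The comparison of SCF with medium asked which genes the hypoxic dendritic cells altered within 6 hours of contact with SCF. None of the 12668 probe sets tested passed an adjusted p of 0.05 in limma, with experiment as a block, and the smallest adjusted p was 0.945. At an unadjusted p under 0.05 there were 533 probe sets, 247 higher and 286 lower with SCF, where 633 were expected with no effect. A plain paired statistic per probe set, adjusted in the same way, also called 0 probe sets. The fitted changes were small throughout, and 0 probe sets reached a 1.5-fold difference in either direction. Among named genes, the largest fitted increase was that of Mir423, a microRNA gene (1.32-fold), and the largest fitted decrease that of Zfp772, a zinc finger gene (0.766-fold). Mir423 rested on D2 and Zfp772 on BC, since their log2 fold changes went from 0.40 to 0.16 without D2 and from −0.38 to −0.24 without BC. Both were chosen after their values were seen, and neither passed the adjusted threshold (adjusted p = 0.945 for each). The 95% confidence interval of the change lay within 1.5-fold in both directions for 12624 probe sets, or 99.7% of those tested. The interval reached beyond 2-fold for 1 probe set. The SCF minus medium difference had the same sign in all 4 experiments for 1630 probe sets (12.9%), where 12.5% is given by chance. In simulated arrays with the spread of these experiments, 82.6% of probe sets changed by 1.41-fold were called among 12668 tested, against 7.45% of those changed by 1.19-fold. Each simulation changed 200 probe sets, by up to 2-fold, and drew probe sets independently. These shares therefore do not cover fewer changes or probe sets that move together. Leaving out 1 experiment moved the fitted change of 18 of the 41 named genes by over 1.5 times or turned it, for 13 of them without BC, 4 without D2, 5 without E and 2 without I.

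Of 6 genes fixed beforehand for their link to SCF, hypoxia or the purification, 4 were tested and none of these passed, while Kitl and Jag2 were too dim to be tested. Kit, the SCF receptor, stood at a log2 intensity of 6.74 ± 0.24 (SD, n = 4) in medium and 6.71 ± 0.26 with SCF. Its log2 fold change was −0.04 (SE 0.06, 95% interval −0.17 to 0.10, limma adjusted p = 0.969), with 2 experiments on each side of 0, and it turned to 0.02 without experiment E. Kitl, which encodes SCF itself, was dim at 3.31 ± 0.06 in medium and 3.22 ± 0.05 with SCF, below the intensity filter of 4.05. Jag2, a Notch ligand, lay below the same filter at 3.59 ± 0.13 in medium and 3.68 ± 0.12 with SCF. Il6, the gene of the inflammatory cytokine interleukin 6, measured 5.87 ± 0.18 in medium and 5.90 ± 0.40 with SCF. Its log2 fold change was 0.04 (SE 0.10, 95% interval −0.19 to 0.26, limma adjusted p = 0.984). In experiment BC Il6 differed by 0.38, and the fitted change turned to −0.08 without BC. Vegfa, a hypoxia-induced angiogenic factor, measured 5.64 ± 0.50 in medium and 5.33 ± 0.28 with SCF. It was lower with SCF in 4 of 4 experiments, with a log2 fold change of −0.31 (SE 0.09, 95% interval −0.53 to −0.10), and did not pass the adjusted threshold (limma adjusted p = 0.945). Without experiment E its log2 fold change was −0.20. Itgax, the gene of CD11c, measured 10.08 ± 0.12 in medium and 10.02 ± 0.23 with SCF, a log2 fold change of −0.06 (SE 0.07, 95% interval −0.22 to 0.09, limma adjusted p = 0.951), which was −0.0039 without BC and −0.11 without D2.

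**Figure D1:**
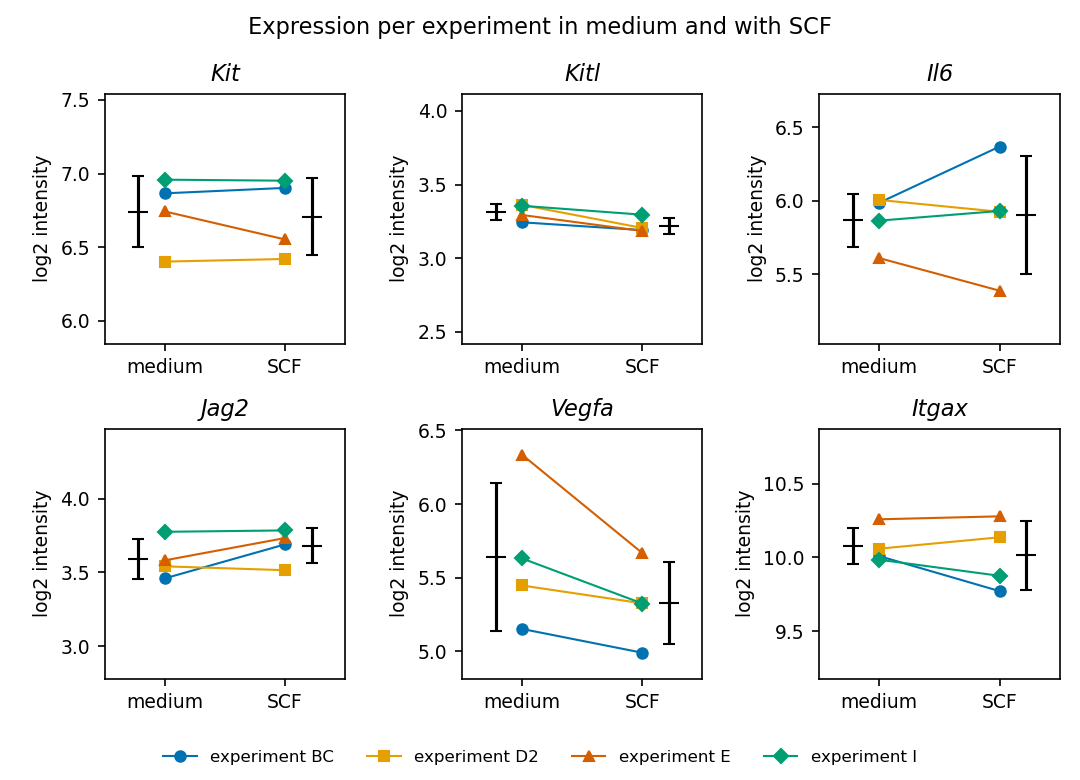
Log2 intensity (vertical axes, each spanning the same number of log2 units) of Kit, Kitl, Il6, Jag2, Vegfa and Itgax in medium and with SCF; coloured symbols joined by lines are the 4 experiments, and black marks with bars are the mean and SD of the 4 arrays of a group. The lines of Vegfa go down in 4 of 4 experiments, while those of Il6 go both ways, with BC at a difference of 0.38.

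Of 39 gene lists tested as groups, 4 passed an adjusted p of 0.05 in limma's camera test with its preset correlation between genes, 2 shifted upward and 2 downward with SCF. None of the 4 held when the correlation was estimated from the data (adjusted p = 0.994 with an estimated correlation for each), and limma's fry test called 0 lists (smallest adjusted p = 0.184). The test with an estimated correlation takes its p from the 3 residual degrees of freedom of the fit, so few lists could pass it. In these 4 lists 0 members passed the threshold, whether adjusted over all probe sets or adjusted over the list alone. The list of pattern recognition receptors, the sensors of microbial products, shifted downward (camera adjusted p = 0.0181), with 23 of 27 measured members below 0 and a mean log2 difference of −0.08 ± 0.11 (SD, n = 4 experiments). Its members with the smallest p were the Toll-like receptor gene Tlr8 at a log2 fold change of −0.36 (SE 0.12), Tlr3 at −0.20 (SE 0.07), the scavenger receptor gene Cd36 at −0.14 (SE 0.05) and the lipopolysaccharide receptor gene Tlr4 at −0.17 (SE 0.07). Without BC, Tlr8 was at −0.22, Tlr3 at −0.13 and Tlr4 at −0.11. At an unadjusted p under 0.05 in limma this list had 6 members, 4 lower and 2 higher with SCF. The matrix and angiogenesis list also shifted downward (camera adjusted p = 0.0299), with 14 of 18 members below 0 and a mean of −0.08 ± 0.09. Vegfa led it, followed by the gelatinase gene Mmp9 at −0.19 (SE 0.06) and the thrombospondin gene Thbs1 at −0.29 (SE 0.10), which was −0.18 without E. The dendritic cell maturation list shifted upward (camera adjusted p = 0.0248), with 20 of 25 members above 0 and a mean of 0.04 ± 0.05. Its leading members were the transporter gene Slco5a1 at 0.19 (SE 0.06), the costimulatory receptor gene Cd40 at 0.16 (SE 0.06), the NF-kB subunit gene Relb at 0.13 (SE 0.05) and the receptor gene Tnfrsf4 at 0.12 (SE 0.05). The MHC class I presentation list shifted upward (camera adjusted p = 0.0391), with 11 of 12 members above 0 and a mean of 0.05 ± 0.01. It was led by the immunoproteasome genes Psmb10 at 0.11 (SE 0.05) and Psmb8 at 0.11 (SE 0.05), the class I transactivator gene Nlrc5 at 0.10 (SE 0.06) and the class Ib gene H2-T23 at 0.08 (SE 0.06). Nlrc5 was at 0.05 without D2 and 0.16 without I, and H2-T23 at 0.04 without E. The number of lists called was 0 without experiment BC, 0 without experiment E, 2 without experiment I and 2 with a stricter intensity filter. The count rose to 6 without experiment D2, 6 with a variance trend and 5 after a repeated quantile normalization. It was 0 in the fit without the replicate block and 0 with experiment as a random block.

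The list means per experiment showed how far the 4 experiments went the same way. Leaving out 1 experiment moved the mean of 36 of the 39 lists by over 1.5 times or turned it (32 without BC, 27 without D2, 17 without E and 22 without I), and equalized array medians moved or turned 35. Equalizing the medians moves all genes of an array alike. With it, the median log2 fold change over the tested probe sets went from 0.00077 to −0.018. A repeated quantile normalization moved or turned 18 lists. The MHC class I mean was above 0 in 4 of 4 experiments, at 0.06 in BC, 0.05 in D2, 0.06 in E and 0.03 in I, although with the array medians equalized it lay above 0 in 3 of 4, with a mean of 0.03. The maturation list differed by 0.11 in BC, −0.00 in D2, 0.03 in E and 0.05 in I, while with the array medians equalized its mean was 0.03, above 0 in 2 of 4, with 0.04 in BC and 0.07 in I. The pattern recognition list differed by −0.24 in BC, −0.02 in D2, −0.08 in E and 0.02 in I. In BC 31 of 39 lists lay below 0, among them monocyte (−0.17) and macrophage markers (−0.14), glycolysis, ribosome biogenesis and interferon genes (−0.13 each). The matrix list differed by −0.17 in BC, 0.02 in D2, −0.12 in E and −0.03 in I, and its mean was −0.05 without BC. With 4 pairs the two-sided exact sign-flip permutation test cannot reach 0.05, and 5 lists stood at the smallest p it allows. Means had the same sign in all 4 experiments in 5 of 39 lists, where 4.88 are given by chance. These were MHC class I and NF-kB targets above 0, and the ERK response, basophil and mast cell lists below 0. With the array medians equalized, of these 5 only the mast cell list had the same sign in all 4. After a repeated quantile normalization, all 5 had the same sign in all 4.

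**Figure D2:**
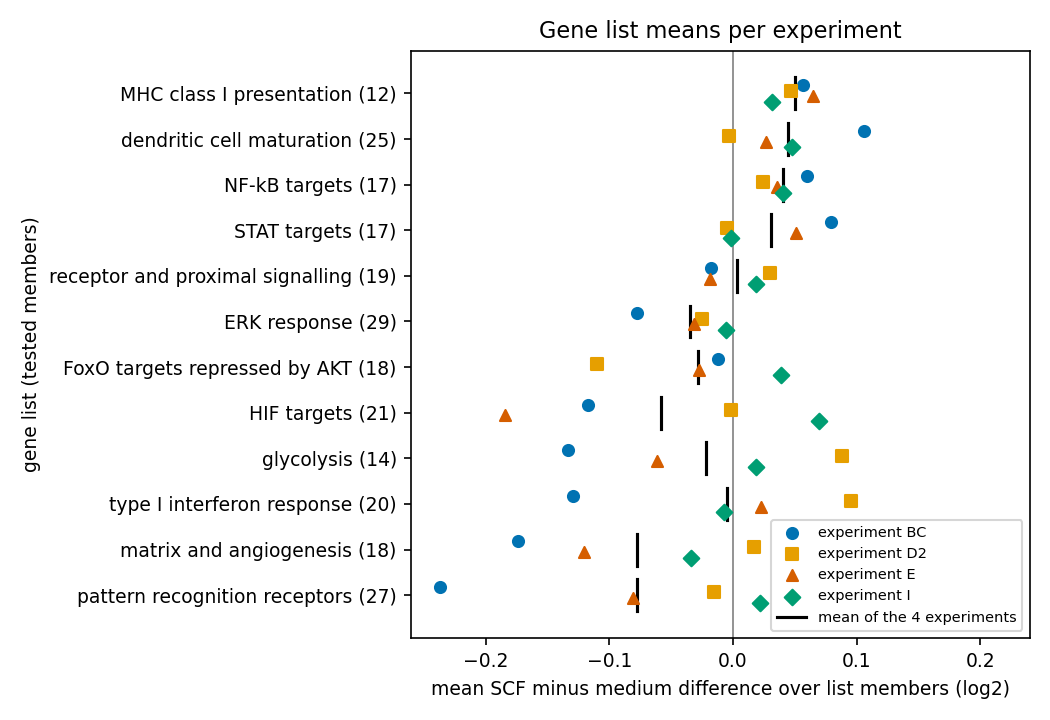
Mean SCF minus medium difference over the members of a gene list (horizontal axis, log2) for 12 of the lists, with the number of tested members in brackets; coloured symbols are the 4 experiments and black bars their mean. The MHC class I means lie between 0.03 and 0.06, and those of pattern recognition receptors between −0.24 and 0.02.

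None of the lists of genes downstream of the SCF receptor passed the list test. The list of the receptor and its proximal signalling proteins had a mean log2 difference of 0.00 ± 0.02 (SD, n = 4 experiments) over 19 members, 11 above 0 (camera adjusted p = 0.949). The adaptor gene Sh2b3 was at 0.09 (SE 0.05) and the ubiquitin ligase gene Cbl at 0.08 (SE 0.05), both above 0 in 4 of 4 experiments, although Cbl in 3 of 4 with the array medians equalized. The ERK response list, early genes induced by the MAP kinase cascade, had a mean of −0.03 ± 0.03 with 20 of 29 members below 0 (camera adjusted p = 0.238), or −0.02 without BC and −0.05 with the array medians equalized. Within it the immediate early gene Egr1 was at −0.21 (SE 0.09), or −0.14 without D2, and the feedback inhibitor gene Errfi1 at −0.10 (SE 0.05). Egr3 was at 0.16 (SE 0.07), between 0.23 and 0.26 in BC, D2 and E but at −0.08 in I. FoxO targets, which AKT signalling represses, had a mean of −0.03 ± 0.06 (camera adjusted p = 0.409), which rested on D2, since it was −0.00042 without D2 and −0.05 without I. Irs2, an insulin receptor substrate gene on that list, was below 0 in 4 of 4 experiments at −0.23 (SE 0.06, limma adjusted p = 0.945). STAT targets had a mean of 0.03 ± 0.04 with 13 of 17 members above 0 (camera adjusted p = 0.239), or 0.01 without BC and 0.01 with the array medians equalized. Among them were Bcl3 at 0.11 (SE 0.05) and the cytokine feedback gene Cish at 0.07 (SE 0.06). The value of Cish rested on BC, where it differed by 0.21 against 0.01 to 0.04 elsewhere, and was 0.02 without BC, but 0.12 as the mean of the gene's probe sets. No member of these 4 lists passed, whether adjusted over all probe sets or adjusted over the list alone.

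No list of hypoxia, metabolic or growth genes passed either. Targets of the hypoxia-inducible factor had a mean of −0.06 ± 0.11 with 14 of 21 members below 0 (camera adjusted p = 0.178). Without E the mean was −0.02 (camera adjusted p = 0.967). The list passed when experiment I was left out (camera adjusted p = 0.00802) and with no intensity filter (0.0204), within a range of 0.00802 to 0.994 over its 16 alternatives. The pyruvate dehydrogenase kinase gene Pdk1 was at −0.19 (SE 0.07) and the glycolytic regulator gene Pfkfb3 at 0.13 (SE 0.06). The glycolysis list had a mean of −0.02 ± 0.10 (camera adjusted p = 0.754), with the hexokinase gene Hk2 at −0.15 (SE 0.08), or −0.08 without BC. The lysosome and phagosome list had a camera adjusted p of 0.178, and passed with the variance trend (0.0442) and without D2 (0.0320) but stood at 0.810 without BC, within a range of 0.0320 to 0.994 over 16 alternatives. Camera adjusted p-values were 0.238 for the unfolded protein response, 0.312 for the ATF4 amino acid response, 0.754 for cholesterol synthesis and 0.949 for fatty acid synthesis. They were 0.949 for lipid efflux genes, 0.993 for the respiratory chain, 0.949 for ribosome biogenesis, 0.611 for genes of the G2 and M phases, 0.949 for S phase genes and 0.959 for apoptosis genes.

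Inflammatory and antigen presentation lists outside the 4 above did not pass. NF-kB targets had a mean of 0.04 ± 0.01, above 0 in 4 of 4 experiments (camera adjusted p = 0.104), with Relb at 0.13 (SE 0.05) and the adaptor gene Traf1 at 0.12 (SE 0.06), or 0.08 without BC and 0.18 without I. With the array medians equalized the mean was 0.02, above 0 in 3 of 4 experiments (camera adjusted p = 0.153). This list passed with the variance trend (camera adjusted p = 0.0397), after a repeated quantile normalization (0.0340) and without D2 (0.0434), within a range of 0.0340 to 0.994 over 16 alternatives. Proinflammatory cytokines had a mean of −0.01 ± 0.04 (camera adjusted p = 0.949). In that list Il1a was at −0.25 (SE 0.10), with its medium array of experiment E far above the others, and at −0.14 without BC and −0.23 without E, and the suppressive cytokine gene Tgfb1 at −0.11 (SE 0.05). Chemokines had a mean of 0.02 ± 0.04 (camera adjusted p = 0.754), with Ccl4 at 0.15 (SE 0.06). The type I interferon response had a mean of −0.00 ± 0.09 (camera adjusted p = 0.949), with the antiviral gene Mx1 at 0.15 (SE 0.06). MHC class II presentation had a mean of −0.00 ± 0.02 (camera adjusted p = 0.993). Its leading member was Marchf1, the ubiquitin ligase gene that lowers surface class II, at −0.18 (SE 0.05) and below 0 in 4 of 4 experiments. Alternative activation genes and Fc receptor and adhesion genes each had a camera adjusted p of 0.754.

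No marker list of the cell types that a bone marrow culture can hold passed the test. Of 13 such lists, 9 had at least 5 members above the intensity filter, and their mean log2 differences lay between −0.04 and 0.01 (camera adjusted p from 0.442 to 0.949). With the array medians equalized all 9 means lay below 0, between −0.06 and −0.01. That scaling moves all genes of an array alike, so these signs are not particular to the markers. The conventional dendritic cell list had a mean of 0.01 ± 0.01 over 20 members, or −0.01 with the array medians equalized, with the transcription factor gene Zbtb46 at 0.16 (SE 0.07). The macrophage list had a mean of −0.02 ± 0.09, with the phagocytic receptor gene Mertk at −0.20 (SE 0.07) or −0.12 without BC, where it differed by −0.46. Of 22 mast cell markers, 6 were bright enough to be tested, and their mean was −0.02 ± 0.01. Among them the transcription factor gene Gata2 was at −0.13 (SE 0.06), or −0.08 without BC. The progenitor list had a mean of −0.00 ± 0.04, with Cd34 at −0.14 (SE 0.06). Cd34 lay near the filter of 4.05, at a mean log2 intensity of 4.13 in medium and 3.99 with SCF. B cell, T and NK cell, eosinophil, and stroma and endothelium markers had between 2 and 4 members above the filter and were not tested as lists. Among lists that watch RNA quality and stress, mitochondrially encoded transcripts (camera adjusted p = 0.949) and heat shock genes (0.409) did not pass, and histone genes had 3 members above the filter. The median, mean and test of a list disagreed in sign in 6 of 39 lists, all with means between −0.02 and 0.01. These were apoptosis, erythroid and megakaryocyte, MHC class II, plasmacytoid dendritic cell, progenitor and proinflammatory cytokine genes.

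The experiment a culture belonged to separated the arrays far more than SCF did. Experiment held 65.2% of the sum of squares over the tested probe sets, or 21.7% per degree of freedom. SCF treatment held 7.97% for its 1 degree of freedom, and the residual 8.95% per degree of freedom. The principal component with the most variance (37.4%) placed both D2 and both E arrays above 0 and both BC and both I arrays below it. SCF minus medium differences of different experiments correlated between −0.32 and 0.30 across the tested probe sets, which are not independent replicates.

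**Figure D3:**
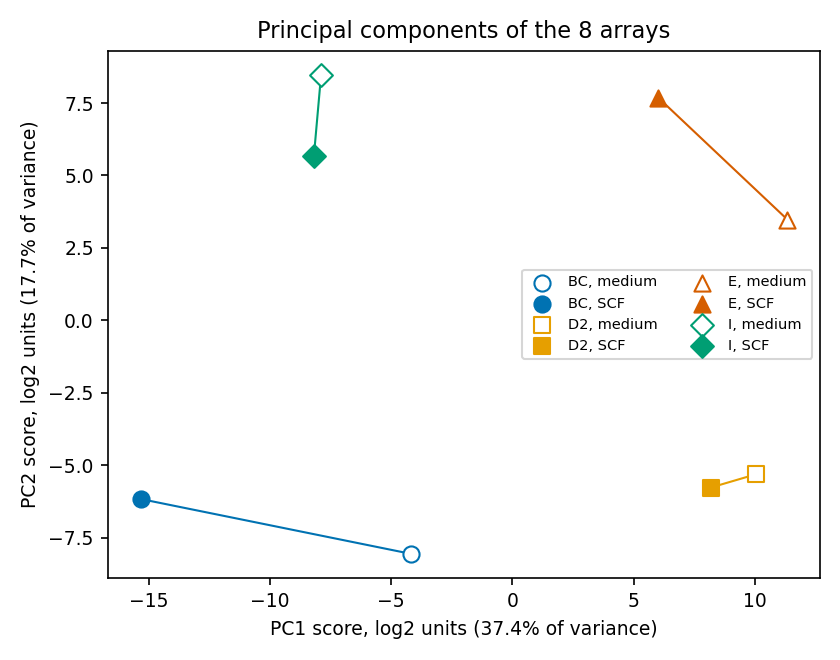
Scores of the 8 arrays on PC1 (horizontal, 37.4% of variance) and PC2 (vertical, 17.7% of variance), both in log2 units over 12668 probe sets; open symbols are medium, filled symbols SCF, and lines join the arrays of 1 experiment. Each experiment takes a region of its own, and the step from medium to SCF on PC1 is largest in BC, from −4.18 to −15.3.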

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

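Tests chosen only after the result was seen were, in this part, the splits counted at an unadjusted p, the interferon test of the MHC class I list, and the use of the fits without BC and with an estimated correlation, which had been fixed beforehand, to weigh 2 lists, with the rule for reading them.

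In 7 of 164 groups of 4 values a single value lay far from the other 3, where chance gives about 8. Egr3 differed by −0.078 in experiment I, against 0.23 to 0.26 in the other experiments. Cish differed by 0.21 in BC, against 0.01 to 0.04 elsewhere. Mertk differed by −0.46 in BC, against −0.14 to −0.09 elsewhere. The log2 intensity of Il1a in medium was 5.35 in E, against 4.58 to 4.69 elsewhere. The mean of the MHC class II list differed by 0.022 in E, against −0.01 in the other experiments. The mean of mitochondrially encoded transcripts differed by −0.068 in D2, against 0.03 to 0.04 elsewhere. The median intensity of the medium arrays was 13.8 in I, against 13.3 to 13.4 elsewhere.

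Other splits of the arrays were counted beside the real one. Of the 8 splits that part all 4 pairs, 4 gave at least as many probe sets at an unadjusted p under 0.05, with 533 in the real split and 1584 in the highest other. In that highest split, the treatment labels of D2 and I were exchanged, and 35 probe sets passed the adjusted threshold, which points to a structure of the samples that sets the SCF minus medium differences of BC and E against those of D2 and I. Whether SCF, exchanged labels or the cultures made it was not tested. Likewise 4 of the 8 called at least as many lists, with 4 in the real split and 8 in the highest other. With 8 splits no share under 0.05 can be reached. Without blocks, 35 of the 35 splits of the arrays into 4 and 4 called at least the 0 probe sets and 0 lists of the real split, which any split must, so this count decides nothing. The highest others were 501 probe sets, when BC and I were set against D2 and E, and 15 lists. That split of the probe sets follows the experiments, a structure of the samples apart from SCF.

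Dendritic cell maturation genes shifted upward and pattern recognition receptors downward, with camera adjusted p-values of 0.0248 and 0.0181, but neither list passed with an estimated correlation (adjusted p = 0.994 for each). In the values as deposited BC contributed most to both, as 53.7% of the maturation shift and 31.8% of the receptor shift were left without BC (camera adjusted p = 0.443 for each). Left were 113% and 98.8% without E (0.0959 for each), 97.4% and 143% without I (0.0896 and 0.00157) and 135% and 127% without D2 (0.00166 and 0.00450). With the array medians equalized, however, the maturation list differed by 0.04 in BC and by 0.07 in I. Whether BC alone carries both cannot be told apart from a wider shift, with over 50% of the maturation shift left. The shift in BC may also be spread between untreated cultures of the same kind, since across the 52 genes of both lists the BC difference correlated at 0.53 (bootstrap 95% interval over genes 0.29 to 0.77) with the main axis of the other 3 untreated arrays, and at 0.49 over all tested probe sets, so this is not particular to the 2 lists. The correlation over the 52 genes was −0.06 for D2, 0.21 for E and 0.31 for I, and genes are not independent replicates. Genes of a list moving together stay open as well, with estimated correlations of 0.24 for the maturation and 0.27 for the receptor list. The loss with an estimated correlation does not decide this, because that test also takes its p from the 3 residual degrees of freedom. The MHC class I list had an estimated correlation of −0.02, and its unadjusted camera p still rose from 0.00401 to 0.0562. A response to SCF remains an open biological explanation, not separated from the others.

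The MHC class I list was higher with SCF in 4 of 4 experiments, with a mean log2 difference of 0.05 ± 0.01, but in 3 of 4 with the array medians equalized, with a mean of 0.03. Equalizing the medians moves all genes of an array alike, so that change is not particular to this list. An interferon response to SCF is a candidate explanation, because interferons induce these genes. The type I interferon list itself had a mean log2 difference of −0.0046 ± 0.094, above 0 in 2 of 4 experiments. It was −0.13 in BC and −0.0075 in I, where the MHC class I mean was above 0, but 0.10 in D2 and 0.02 in E. Its spread between experiments is wider than the shift to be explained, so a type I interferon response cannot be told apart from its absence. A response to other interferons was not tested. Array scaling may contribute, since with the array medians equalized the camera adjusted p of the list was 0.0799, within a range of 0.00532 to 0.994 over 16 alternatives. After a repeated quantile normalization, however, the list passed, with a mean of 0.05, above 0 in 4 of 4 experiments.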

How the results depend on the processing

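No alternative was added after the data were seen. The count of probe sets past the threshold was 0 under all 15 alternatives tried for it, and the count at an unadjusted p under 0.05 ranged from 125 (no replicate block) to 856 (no intensity filter, with more probe sets tested). The blocked and unblocked fits both gave 0 probe sets, while without the replicate block 0 lists were called against 4 with it, and the block changed no other call. Lists called numbered 0 with an estimated correlation, which uses the 3 residual degrees of freedom, and 0 with fry. They numbered 0 with experiment as a random block and 2 with the stricter filter, which tested fewer genes. They ranged from 0 to 6 when each experiment was left out in turn, with 0 without BC, 0 without E, 2 without I and 6 without D2. The cause of these differences was not tested, and the fits without an experiment also had fewer samples. With array medians equalized 1 list was called upward and 2 downward, and after repeated quantile normalization 3 upward and 2 downward, against 2 and 2 as deposited. The 4 called lists kept their direction under every alternative, and each passed in 6 to 9 of 16. Lists with the same sign in every experiment numbered 1 with array medians equalized, 5 after repeated quantile normalization, and 7 to 15 with an experiment left out, where 3 signs agree more often than 4. The treatment share was 10.4% to 13.01% with an experiment left out, against 7.97%, since fewer arrays leave fewer degrees of freedom to share. Of 491 values of named genes under the alternatives, 489 kept their direction. Kit ranged from −0.060 to 0.016 and Il6 from −0.079 to 0.12 with an experiment left out, turning without E and without BC, and the cause was not tested. Signal over background is unknown for these values.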

Other observations

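Tests chosen only after the result was seen were, in this part, the F test between experiments and its lists, the plasmacytoid markers without Cox6a2, and the test for exchanged arrays, for which similar correlations were already known.

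The 4 preparations differed in single interferon and hypoxia genes, in a test over the arrays of both groups, while as lists these did not pass with an estimated correlation (adjusted p = 0.485 for interferon genes in E and 0.497 for hypoxia targets in BC). That list test has few residual degrees of freedom, so its failure does not show that the lists were alike. Between experiments 424 probe sets differed (limma F test, adjusted p under 0.05), highest in E for 169 of them and lowest in I for 146. Each experiment is 1 preparation with 2 arrays, so this test measures only the spread within preparations. Of 20 type I interferon genes tested, 9 differed and all 9 were highest in E. The antiviral gene Oasl2 had a mean log2 intensity of 7.65 in E against 6.30 to 6.52 in the others (adjusted p = 0.00740), and Irf7, a master regulator of interferon genes, 6.41 against 4.92 to 5.17 (adjusted p = 0.0125). Targets of the hypoxia-inducible factor spread as well, with 9 of 21 differing, 8 of them highest in E and lowest in BC. Ak4, an adenylate kinase gene, measured 5.15 in BC against 6.51 to 6.95 (adjusted p = 0.0144), and the oxygen sensor gene Egln3 4.71 against 5.68 to 6.66 (adjusted p = 0.0201). The mean of the hypoxia list, centred over the arrays, was lowest in BC in both groups (−0.23 in medium, −0.35 with SCF), but highest in E in medium (0.29) and in I with SCF (0.15, against 0.11 in E), and was not tested within a group. All cultures were held at the same nominal 2% oxygen.

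Of 12 macrophage markers 3 differed, all highest in E, and of 21 ATF4 amino acid response genes 6 differed, 4 of them highest in E (adjusted p = 0.497 for each list in E with an estimated correlation). The monocyte and macrophage receptor gene Cd14 measured 6.01 in E against 4.78 to 5.29 (adjusted p = 0.0124), and the high-affinity Fc receptor gene Fcgr1 8.70 against 7.69 to 8.25 (adjusted p = 0.0360). Asns, the asparagine synthetase gene induced by ATF4, measured 7.87 in E and 7.77 in D2, against 7.36 in BC and 7.11 in I (adjusted p = 0.0149). Cholesterol synthesis genes lay lowest in I, by a mean log2 difference of −0.21, with 1 of 19 members differing. Set against the other experiments, the camera adjusted p of the interferon list in E was 2.46e-26, that of hypoxia targets in BC 9.54e-10, that of pattern recognition receptors in E 1.22e-07, that of cholesterol synthesis in I 2.81e-06 and that of matrix and angiogenesis genes in E 3.78e-05. None of these held with an estimated correlation (adjusted p = 0.485 for the interferon list and 0.497 for each of the others). That test takes its p from the few residual degrees of freedom of the fit, so the loss does not decide whether the lists differed. For these list tests each experiment was set against the others pooled, with treatment but no experiment block in the fit. The 2 arrays of 1 preparation thus counted as separate replicates. The pattern recognition and matrix lists are also 2 of the 4 called for SCF. These genes were chosen after their values were seen.

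The interferon list was higher in E by a mean log2 difference of 0.60, or 1.51-fold, and 16 of 20 genes were higher on both E arrays than on all others. The tables argue against normalization of the arrays, which left 98.4% to 102% of the difference after quantile normalization or median centring. Over the tested probe sets they argue against arrays exchanged between experiments, since outside the interferon list the deviations of the 2 E arrays correlated at 0.41, and those of an E array and any array of the other group from another experiment at 0.32 at most (bootstrap 95% interval of the difference over probe sets 0.05 to 0.13, which treats probe sets as independent), although over all 41345 probe sets, where 1 of 8 arrays was closest to its own experiment, r was 0.9944 between the E arrays, 0.9949 between the E array with SCF and the I array in medium and 0.9947 between the medium arrays of E and BC. A general inflammatory activation stays open, since the lists went different ways. NF-kB targets were not higher in E, at −8.95% of the interferon list's difference (bootstrap 95% interval over genes −15.5% to −2.14%). Proinflammatory cytokines stood at 22.8% (−5.87% to 51.4%). Macrophage and pattern recognition lists were higher in E by 0.29 and 0.26, while the dendritic cell maturation list was lower, at −0.08. More plasmacytoid dendritic cells may contribute and stay open too, although the design names no biological difference for E. Whether the purification on CD11c removes such cells was not tested. Of 11 tested markers, 10 lie outside the interferon list and stood at 21.2% of its difference (interval −10.4% to 61.2%), or 4.61% without Cox6a2. Cox6a2 was at 1.02, Lair1 at 0.36, Tlr7 at 0.26, Cd300c at 0.08, Tcf4 at 0.02 and Irf8 at 0.00. Pacsin1 was at −0.03, Tlr9 and Ly6d at −0.06 and Spib at −0.32, and 4 of the 11 are also on other lists.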
